A study of Sus scrofa with 6 samples.

How the data were processed

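Poly(A) RNA of pig 4-cell embryos was measured in 6 libraries, 3 from embryos cultured at 38.5 °C (control) and 3 from embryos cultured at 41.5 °C (high temperature) for 4 days. Per the labels' protocols, oocytes were activated with 2 direct-current pulses of 120 V, mRNA was captured on oligo(dT) beads and libraries were made with the SMART-Seq v4 kit, which does not mark strand. Each library was assigned to its group by its label. Nothing in the labels says whether the replicates came from separate cultures.

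The read counts per gene were deposited by the authors as whole numbers, not normalized, per the file headers. The FPKM values (fragments scaled by gene length and library size) and the TPM values (transcript abundances scaled to the same total in each library) were computed by the authors and deposited beside the counts, per the file headers. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, HISAT, Bowtie2, StringTie 2.1.3b and the genome build Sscrofa11.1, without saying which did what. The tool that counted the reads and its rule for overlapping genes are not given in the sources used here. Reads of overlapping genes or near-identical copies may therefore have been assigned to either. Each column of the series table was checked against the FPKM of the sample's own table, and 99.4% to 99.5% of 30376 genes were equal within 1e-05 in their own column against at most 27.9% in any other.

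The table held 30376 genes, of which 24 had no symbol (mitochondrial tRNA and rRNA, 0.527% to 0.658% of the counts of a library). They were kept in the main test and left out in an alternative. Gene identifiers were matched by Entrez ID to a RefSeq gene table of Sscrofa11.1 (30352 matched, 30324 at the same position), from which positions and overlaps of gene spans were taken. The total count per library was 28114005 to 30079385 reads. Intervals and floors that rest on reads alone cover counting error only, and the floor of a gene with no reads was set at 3 counts over the summed depth of the group.

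Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on the counts as deposited, with TMM scaling, the default expression filter (16056 genes kept), group as the single term and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 32 lists. The estimate was 0.88 for ribosomal proteins and for mitochondrially encoded transcripts, 0.65 for translation factors and 0.53 for nuclear genes of oxidative phosphorylation. It was 0.52 for ribosome biogenesis, 0.51 for oocyte transcripts and 0.38 for genome activation markers. Splicing factors were at 0.3, the proteasome at 0.24 and mitochondrial dynamics at 0.19. The preset takes such members as nearly independent, so the adjusted p it gives for these lists is too small. The lists, 5 of them primary, were the heat shock response, genome activation markers, oocyte transcripts, DNA methylation, histone methylation enzymes, histone acetylation enzymes, maternal mRNA decay, endoplasmic reticulum stress, immediate early genes, apoptosis, p53 targets, autophagy, antioxidant defence, nuclear and mitochondrial genes of oxidative phosphorylation, mitochondrial dynamics, glycolysis, lipid handling, ribosomal proteins, ribosome biogenesis, RNA polymerase II transcription, splicing, translation factors, proteasome, mitosis, DNA replication, DNA damage response, pluripotency, adhesion, imprinted genes, and markers of cumulus and of stromal and blood cells. Single values per library were compared with exact permutation tests, two-sided, for which 3 against 3 libraries allow no p below 0.1.

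The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named called genes by size of change and, as no gene was called, the 10 genes with a symbol and the smallest unadjusted p. It also named 13 genes whatever their result: HSPA8, HSPH1, HSP90AA1, HSP90AB1, DNAJB1, HSF1, EIF1AX, POU5F1, GDF9, BMP15, DNMT1, TET3 and KDM5B.

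The tests were tried on simulated counts with the means, the spread of each gene and the library sizes of this comparison and 200 changed genes. Genes were drawn independently, so variation shared across the genes of a real library was absent. With edgeR these counts gave 864, 923 and 950 genes at an unadjusted p below 0.05, against 297 in the real data. The shares found and the false calls may therefore differ in the real libraries. At 2-fold, 4-fold and 8-fold changes edgeR recovered 0%, 69% and 93.5% of the changed genes with 0, 9 and 13 false calls. DESeq2 1.42.0 recovered 13%, 82% and 97.5% with 22, 52 and 58 false calls. The 95% intervals of edgeR held the true value for 95%, 95.1% and 94.7% of the genes above 4 CPM, and coverage below 4 CPM was not checked.

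Alternatives fixed beforehand were the replicate number as a block, DESeq2, its size factors in edgeR, no scaling beyond the library total, no filter on low counts, a minimum absolute log2 fold change of 1, limma on log2(FPKM + 1) and log2(TPM + 1) with a value of at least 1 in 3 libraries, and each library left out in turn. Added after the data were seen were a covariate from the oocyte and genome activation lists, the first component of the deviations from the group means as a covariate, 1 surrogate variable from svaseq (sva 3.50.0), a robust fit, nuclear genes only and, for the oxidative phosphorylation list, 16 members matched by product name that stood under another symbol. The other lists were matched by symbol alone.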

Results

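Poly(A) RNA was sequenced from pig embryos at the 4-cell stage that had developed from electrically activated oocytes. The embryos were cultured for 4 days either at 38.5 °C, the control temperature (3 libraries), or at 41.5 °C, the high temperature (3 libraries). The question stated for the series is how high temperature affects the activation of the embryonic genome, the switch from stored oocyte transcripts to transcripts made by the embryo. The total count per library lay between 28114005 and 30079385 reads assigned to genes, and 16056 of the 30376 annotated genes had enough reads to be tested. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

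Embryos cultured at 41.5 °C had lower counts of WISP3 and LSMEM2 and higher counts of MOGAT1 in every library. No gene passed the adjusted threshold of the edgeR test with group as the single term, while DESeq2 called these 3 (adjusted p = 7.86e-15, 4.12e-07 and 1.8e-06) and WDR76 (0.036). With the replicate number as a block, edgeR also called these 3 (adjusted p = 0.00758, 0.0318 and 0.0371). WISP3, a secreted protein of the CCN family, was at 13.4 ± 3.99 CPM (SD, n = 3) in controls and at 0.867 ± 0.413 CPM (SD, n = 3) at high temperature, 15.5-fold lower. LSMEM2, a membrane protein with a leucine-rich segment, was at 2.66 ± 0.385 CPM in controls and 0.213 ± 0.0992 CPM at high temperature, 12.2-fold lower. MOGAT1, an acyltransferase of triglyceride synthesis, had 0 counts in all 3 control libraries and 74, 33 and 101 counts at high temperature, at least 66-fold higher against a floor of 3 counts over the control group. PTTG1 (securin, which until anaphase inhibits separase, the protease that frees sister chromatids) was among the most abundant transcripts. It was 1.59-fold lower at high temperature, at 5330 ± 422 CPM against 8490 ± 513 CPM. WDR76, a WD-repeat protein, was 1.79-fold lower, at 97.2 ± 3.57 CPM against 173.9 ± 13.7 CPM.

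The log2 fold changes, high temperature against control, were -3.95 (standard error 0.41) for WISP3, -3.61 (0.42) for LSMEM2, -0.84 (0.17) for WDR76 and -0.67 (0.16) for PTTG1. The edgeR quasi-likelihood adjusted p was 0.174 for WISP3 and for LSMEM2, 0.515 for MOGAT1 and 0.999923 for WDR76 and PTTG1. The other 5 of the 10 genes with the smallest p were higher at high temperature in all 3 libraries. They were IGF2 (3.23-fold, an imprinted growth factor gene), PRR12 (2.58-fold), INSM2 (4.84-fold), ARMC7 (3.97-fold) and TMEM8A (3.18-fold), each at under 10 CPM in both groups. These counts were low, from 5 to 17 reads per control library for IGF2 and INSM2, and the edgeR adjusted p of each of the 5 was 0.999923.

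**Figure D1:**
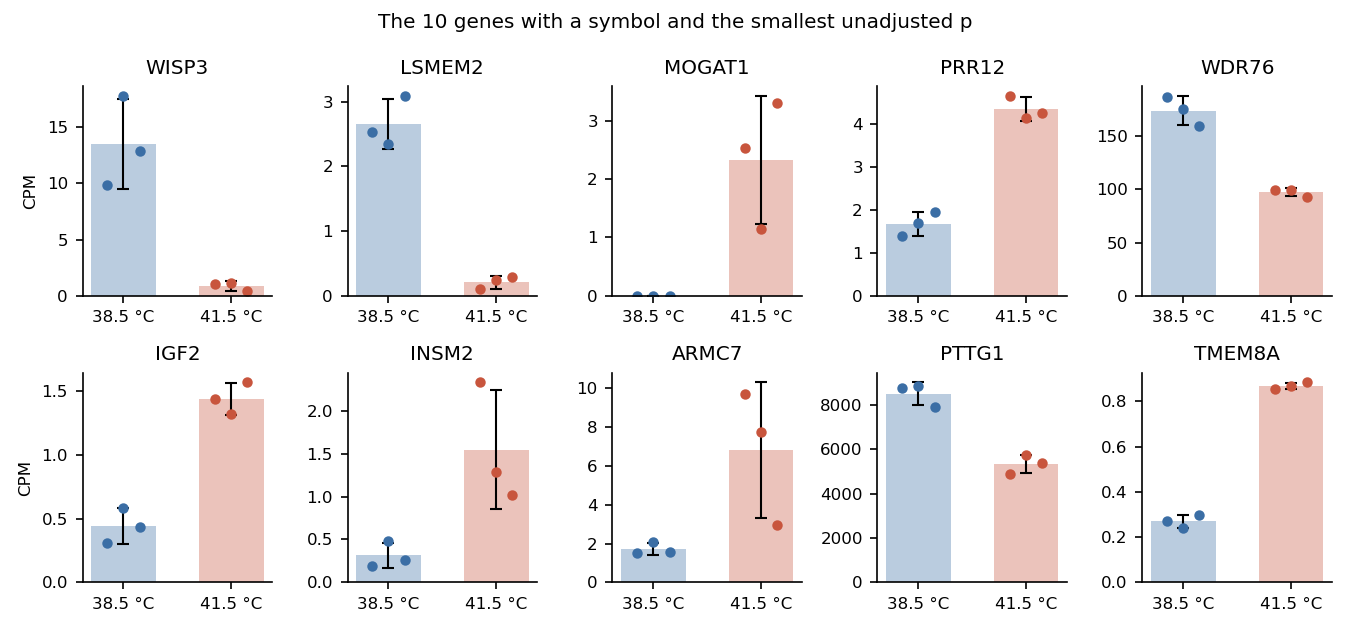
CPM (y axis, counts scaled to library size, linear, from 0) of the 10 genes with a symbol and the smallest unadjusted p in embryos cultured at 38.5 °C and 41.5 °C. Points are libraries, bars are means and error bars are SDs (n = 3), and in all 10 genes the libraries of the groups do not overlap, as in MOGAT1 with 0 CPM in all 3 controls.

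Of these 10 genes 8 overlap another counted gene in the annotation, and for MOGAT1, LSMEM2 and WISP3 the interval of the summed count of the overlapping genes held 0. MOGAT1 (chromosome 15, 124568449 to 124607925, Sscrofa11.1) lies almost wholly within the span of LOC100523928, a glycerol kinase pseudogene (124565266 to 124607923). LOC100523928 was at 7.14 ± 0.979 CPM in controls and 4.68 ± 0.607 CPM at high temperature, and the sum of both was at 7.14 ± 0.979 and 7 ± 0.792 CPM (SD, n = 3). LSMEM2 (chromosome 13, 32752515 to 32757042) overlaps IFRD2 (32756671 to 32790763), and their sum was at 8.99 ± 2.78 CPM in controls and 9.20 ± 3.27 CPM at high temperature. WISP3 (chromosome 1, 78005442 to 78020595) overlaps TUBE1 (78018113 to 78048466), which was at 66.4 ± 6.04 CPM in controls and 69.6 ± 16 CPM at high temperature, and the sum of WISP3 and the 2 genes overlapping it was at 79.9 ± 9.63 and 70.6 ± 15.6 CPM. WDR76 (chromosome 1, 127651765 to 127741357) overlaps FRMD5, which had 21 to 130 counts per library, and the sum of WDR76 and FRMD5 was at 176 ± 13.3 CPM in controls and 101 ± 3.03 CPM at high temperature. PTTG1 (chromosome 16, 63104698 to 63112382) and IGF2 (chromosome 2, 1469183 to 1496417) overlapped no other counted gene. The log2 fold change of the sum was -0.03 (95% interval -0.55 to 0.50) for MOGAT1, 0.03 (-0.75 to 0.81) for LSMEM2, -0.18 (-0.70 to 0.35) for WISP3 and -0.81 (-1.2 to -0.41) for WDR76. INSM2 overlaps RALGAPA1, ARMC7 overlaps JPT1 and NT5C, and TMEM8A overlaps MRPL28 and NME4. For these 3 the interval of the sum also held 0. It held as well the sums predicted with the overlapping genes unchanged (0.033, 0.05 and 0.11), so the sums decide nothing for these 3. The interval of PRR12 with PRRG2 was 0.65 to 1.9. For WDR76 and PRR12 the log2 fold change of the sum (-0.81 and 1.3) lay close to that of the gene alone (-0.84 and 1.37). The values of the other 6 overlapping genes are uncertain, since the library kit does not mark strand and the rule by which reads of overlapping genes were counted is not given in the sources used here.

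**Figure D2:**
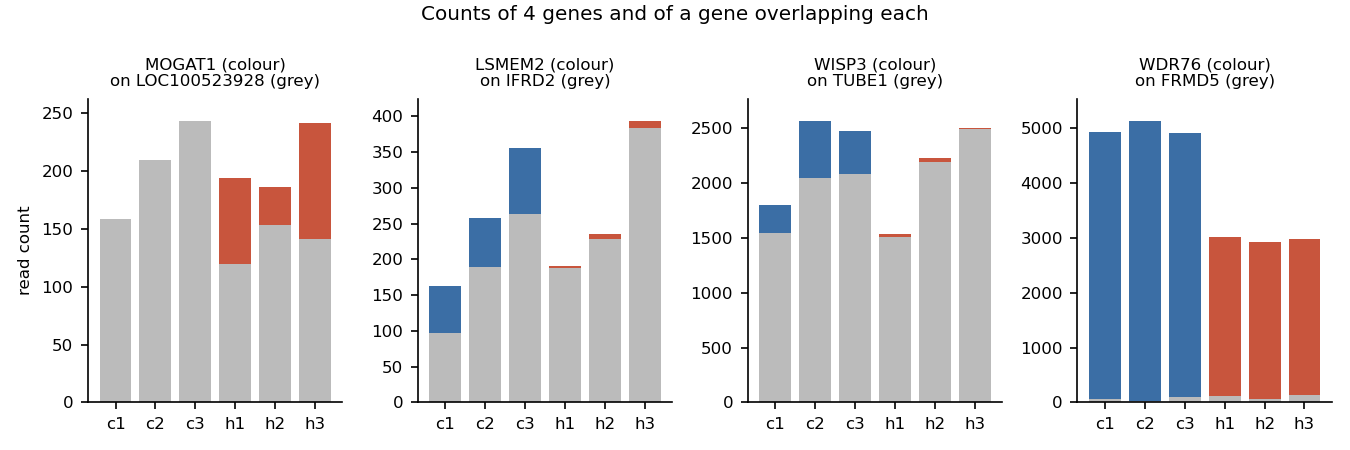
Read counts (y axis) per library of MOGAT1, LSMEM2, WISP3 and WDR76 (blue in controls c1 to c3, red at high temperature h1 to h3) stacked on the counts of a gene whose span overlaps each (grey). MOGAT1 has 0 counts in c1 to c3 and 33 to 101 in h1 to h3, while the grey LOC100523928 has 159 to 243 in c1 to c3 and 120 to 153 in h1 to h3.

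By the edgeR quasi-likelihood test 0 genes had an adjusted p below 0.05, with 297 genes at an unadjusted p below 0.05 where chance alone gives about 803, and DESeq2 called 5 genes (2 higher: MOGAT1 and LOC110262067; 3 lower: WISP3, LSMEM2 and WDR76). In 1238 genes (7.71%) the 3 libraries of a group all lay above those of the other, where chance gives 10%. On simulated counts of this comparison with 200 changed genes, the edgeR test found 0% of 2-fold, 69.0% of 4-fold and 93.5% of 8-fold changes, and DESeq2 found 13% of the 2-fold changes with 22 false calls. The simulated genes varied independently and gave edgeR 864 to 950 genes at an unadjusted p below 0.05, so these shares may not hold for the real libraries. The 95% interval of the fold change excluded a 4-fold change in either direction for 91.7% of the tested genes and a 2-fold change for 49.7%. Coverage of these intervals was checked on simulated counts only for genes above 4 CPM.

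Heat shock genes showed no called difference in embryos cultured at 41.5 °C. Their list holds chaperones and regulators, some induced on heating and some constitutive. Of the 28 measured members of the heat shock response list, 0 passed the test, over all genes and adjusted over the list alone, with 10 higher and 18 lower. HSPA8, the constitutive cytosolic HSP70, was at 608 ± 217 CPM in controls and 572 ± 211 CPM at high temperature (SD, n = 3). HSPH1 was at 128 ± 36.3 and 117 ± 22.5 CPM, HSP90AA1 at 1003 ± 163 and 1107 ± 88.8 CPM, and HSP90AB1 at 146 ± 38.4 and 159 ± 24.1 CPM. DNAJB1, an HSP40 co-chaperone, was at 160 ± 27.5 CPM in controls and 183 ± 36.3 CPM at high temperature, and the factor HSF1, which switches on heat shock genes, at 2.52 ± 0.486 and 3.10 ± 0.130 CPM. HSP70.2, an HSP70 gene named after its values were seen, was at 9.95 ± 0.163 CPM in controls and 13.3 ± 3.31 CPM at high temperature, with values of 17.0, 11.8 and 10.9 CPM in the 3 heated libraries.

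The upper end of the 95% interval lay below a 2-fold rise for 25 of the 28 heat shock genes and below a 4-fold rise for 27. It was a log2 fold change of 0.73 for HSPA8, 0.46 for HSPH1, 0.58 for HSP90AA1, 0.70 for HSP90AB1, 0.72 for DNAJB1 and 0.89 for HSF1. The list's median log2 fold change was -0.12, and 0.0054 and 0.0019 on the log2(FPKM + 1) and log2(TPM + 1) scales, and the set test against the other genes missed the threshold (camera, adjusted p = 0.51). Without control replicate 1 the median was 0.03, and without high-temperature replicate 3 it was 0.06.

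**Figure D3:**
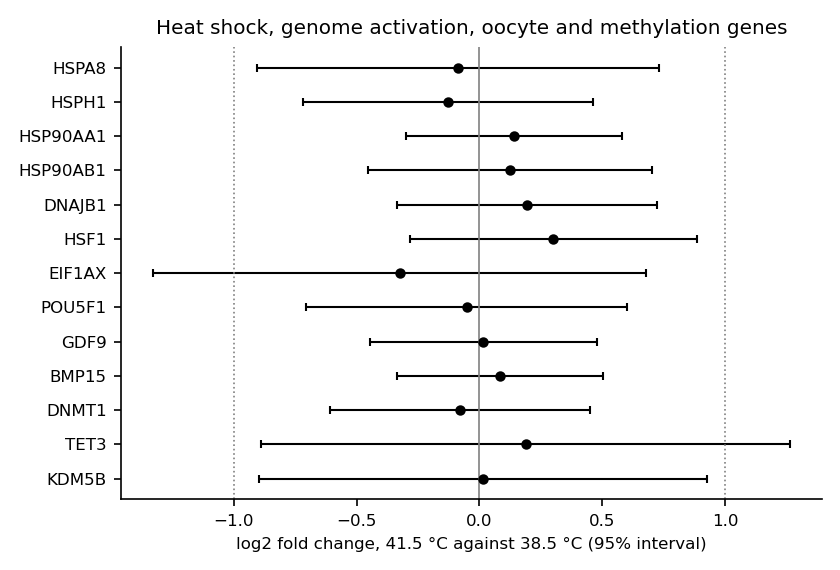
Log2 fold change (x axis) at 41.5 °C against 38.5 °C for 13 genes fixed before the data were examined, from the heat shock, genome activation, oocyte, pluripotency and DNA methylation groups. Points are edgeR estimates, bars are 95% intervals, dotted lines mark a 2-fold change, and every interval holds 0.

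Markers of genome activation did not pass the test either. Of 24 measured members 0 passed, over all genes or adjusted over the list alone, with 7 higher and 17 lower at high temperature. EIF1AX, a translation initiation factor listed as a marker of embryonic transcription, was at 654 ± 350 CPM in controls and 523 ± 217 CPM at high temperature (SD, n = 3). KDM5B, a histone H3 lysine 4 demethylase, was at 30.6 ± 12.3 and 30.9 ± 13.2 CPM. Among members named after their values were seen, DPPA3 was at 1841 ± 527 CPM in controls and 1347 ± 173 CPM at high temperature, DPPA4 at 7.04 ± 2.26 and 4.70 ± 1.17 CPM, and DPPA2 at 393 ± 245 and 257 ± 121 CPM. The list's median log2 fold change was -0.11, and 0.0081 with no scaling beyond the library total (camera, adjusted p = 0.335). Without control replicate 1 the median was 0.08 and without high-temperature replicate 3 it was 0.07, while the list was called lower without control replicate 3 (adjusted p = 0.0232) and without high-temperature replicate 1 (0.0045).

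Transcripts inherited from the oocyte also showed no called difference, with 16 of 31 measured members higher, 15 lower and 0 past the test, over all genes or adjusted over the list alone. GDF9 and BMP15, growth factors secreted by the oocyte, were at 120 ± 18.3 and 838 ± 105 CPM in controls and at 121 ± 13.3 and 888 ± 81.2 CPM at high temperature (SD, n = 3). The median log2 fold change was 0.0069, and -0.0023 with DESeq2 size factors, while the mean of -0.02 and the set test pointed down (camera, adjusted p = 0.902). Without control replicate 1 the oocyte list was called lower (median -0.15, adjusted p = 0.00376), and without high-temperature replicate 3 the median was -0.11 (adjusted p = 0.109). The direction was the other way without control replicate 3, with 22 higher and 9 lower (median 0.13, adjusted p = 0.0902), and without high-temperature replicate 1, with 20 higher and 11 lower (median 0.06, adjusted p = 0.287). POU5F1, a pluripotency factor, was at 44.1 ± 14.9 CPM in controls and 42.6 ± 4.18 CPM at high temperature.

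Among genes of DNA methylation, 8 of 18 members were higher, 10 lower and 0 past the test, over all genes or adjusted over the list alone, and the median log2 fold change of -0.07 was 0.03 with no scaling beyond the library total. DNMT1, the maintenance DNA methyltransferase, was at 8535 ± 1621 CPM in controls and 8075 ± 1749 CPM at high temperature, and TET3, which oxidizes methylcytosine in the zygote, at 13.8 ± 7.99 and 15.7 ± 6.50 CPM (SD, n = 3). Of 37 histone methyltransferases and demethylases 24 were higher and 13 lower, again with 0 past the test, over all genes or adjusted over the list alone. In 5 of these, named after their values were seen, the libraries of the groups did not overlap, where chance gives 10%: KMT5C, KMT2C and EHMT2 were higher in all 3 heated libraries (1.98-fold, 1.18-fold and 2-fold) and KDM4A and KDM1A lower (1.48-fold and 1.1-fold). The camera adjusted p was 0.696 for DNA methylation, 0.298 for the histone methylation enzymes and 0.298 for the histone acetylation enzymes (13 of 23 higher).

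Immediate early genes, transcription factors and regulators that cells induce within minutes of a stimulus, were higher as a group at high temperature than the other genes tested. Of 16 measured members 11 were higher and 5 lower, with a median log2 fold change of 0.50 (limma camera with a preset correlation of 0.01, adjusted p = 0.000292). The call was lost with an estimated correlation (adjusted p = 0.285). That estimate was -0.017, below the preset, so correlation between members does not account for the loss. The list was not called by fry either (adjusted p = 0.146). By camera with the preset correlation the call held without each library in turn. Without high-temperature replicate 1 the median was 0.29, with 10 members higher and 6 lower (adjusted p = 0.00922). On the log2(FPKM + 1) scale the median was 0.32, where only 6 members had values high enough to be tested. No member passed by itself, over all genes or over the list alone. Among members named after their values were seen, JUNB was at 0.213 ± 0.0678 CPM in controls and 0.589 ± 0.154 CPM at high temperature (SD, n = 3), IER5 at 1.19 ± 0.435 and 2.05 ± 0.445 CPM, and DUSP1, a phosphatase of MAP kinases, at 60.3 ± 17.5 and 85.0 ± 27.7 CPM. The summed cumulus and granulosa cell markers also had a higher mean at high temperature, 52.0 ± 4.99 CPM against 45.5 ± 3.29 CPM (SD, n = 3; exact permutation test, two-sided p = 0.2), and that list was called higher on the FPKM and TPM scales. The median abundance of the immediate early list was 1.88 CPM, and its median lay above the 95% range (-0.20 to 0.19) of 10000 random lists matched on abundance and transcript length.

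Nuclear genes of oxidative phosphorylation were lower as a group, with 29 of 33 measured members lower, 4 higher and a median log2 fold change of -0.25 (camera, adjusted p = 0.00105). With the estimated correlation of 0.53, far above the preset of 0.01, the call was lost (adjusted p = 0.812), as it was by fry (0.892). The call rested on control replicate 1 and high-temperature replicate 3. These 2 libraries were also the extremes of the ribosomal list mean (7.28 and 5.66 log2 CPM) and of 18S ribosomal RNA (105 and 968 CPM), and a link was not tested. Without the first of these the median was 0.03 (camera, adjusted p = 0.929), and without the second it was -0.05 (adjusted p = 0.349). The median was -0.13 with no scaling beyond the library total and -0.11 on the log2(FPKM + 1) scale. Of the 50 listed genes 16 stood in the table under an older symbol or a locus name and were added, by product name, after the data were seen. With them 42 of 49 members were lower (median -0.25, camera adjusted p = 0.000146, and 0.812 with an estimated correlation). The median of these 49 was 0.03 without control replicate 1 (adjusted p = 0.839) and -0.03 without high-temperature replicate 3 (0.286). No member matched by symbol passed the test, over all genes or over the list alone. NDUFB1 and NDUFA6, subunits of complex I named after their values were seen, were at 36.0 ± 5.06 and 72.1 ± 8.55 CPM in controls and at 21.8 ± 2.70 and 48.9 ± 8.36 CPM at high temperature (SD, n = 3). All 13 mitochondrially encoded transcripts had a log2 fold change above 0, with a median of 0.08 (camera, adjusted p = 0.335), and the list was called higher on the FPKM scale (adjusted p = 1.21e-06) and without control replicate 1 (0.00402). Without control replicate 3 the median was 0.01, with 7 higher and 6 lower (adjusted p = 0.934). Leaving out high-temperature replicate 1 gave a median of 0.02, with 9 higher and 4 lower (0.708). Together they took 22.0 ± 1.38% of all counts in controls and 25.1 ± 1.46% at high temperature, without overlap (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow).

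Proteasome genes had 24 of 34 members lower and a median log2 fold change of -0.22, and the list missed the threshold (camera, adjusted p = 0.0592). Its median was 0.06 without control replicate 1 and 0.04 without high-temperature replicate 3. The list was called lower without high-temperature replicate 1 (adjusted p = 0.000191), without control replicate 3 (0.00241), without control replicate 2 (0.0374), with no filter on low counts (0.0365) and with the replicate number as a block (0.00156). These calls are from camera with the preset correlation of 0.01, while the estimate was 0.24, so their adjusted p are too small. Over all 6 libraries the adjusted p was 0.812 with the estimated correlation and 0.892 by fry. PSMB6, a catalytic subunit named after its values were seen, was at 87.5 ± 16.1 CPM in controls and 49.7 ± 9.28 CPM at high temperature (SD, n = 3). Genes of DNA replication and mitosis also missed it (camera, adjusted p = 0.2 and 0.236), with 28 of 41 and 26 of 35 members lower. The median of the replication list was 0.00038 with no scaling beyond the library total. Of all genes over 64 CPM, which include both genes named below, only 23.6% were higher at high temperature. The list medians lay at percentiles 15.52 and 11.23 of random lists matched on abundance, so neither list stood out from genes of like abundance. Both lists were called lower without control replicate 1 (adjusted p = 0.0432 and 0.0378). Leaving out control replicate 3 gave 18 higher and 23 lower members of the replication list, and 15 and 20 of the mitosis list. PCNA, the sliding clamp of replication, was at 6159 ± 861 CPM in controls and 4653 ± 558 CPM at high temperature, and CCNB1, the mitotic cyclin B1, at 651 ± 47.8 and 498 ± 18.1 CPM, both named after their values were seen. Of 83 ribosomal protein genes 65 were lower, with a median of -0.16 that was 0.002 on the FPKM scale (adjusted p = 0.2). Without control replicate 1 the ribosomal list was called higher (median 0.40, adjusted p = 4.42e-06), and it was called lower without high-temperature replicate 1 (median -0.56, adjusted p = 4.91e-09), control replicate 3 (-0.48, 1.16e-08) or control replicate 2 (-0.31, 0.00836). It was also called lower with the replicate number as a block (0.0139). The estimated correlation within this list was 0.88, so these adjusted p, from camera with the preset correlation of 0.01, are too small.

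**Figure D4:**
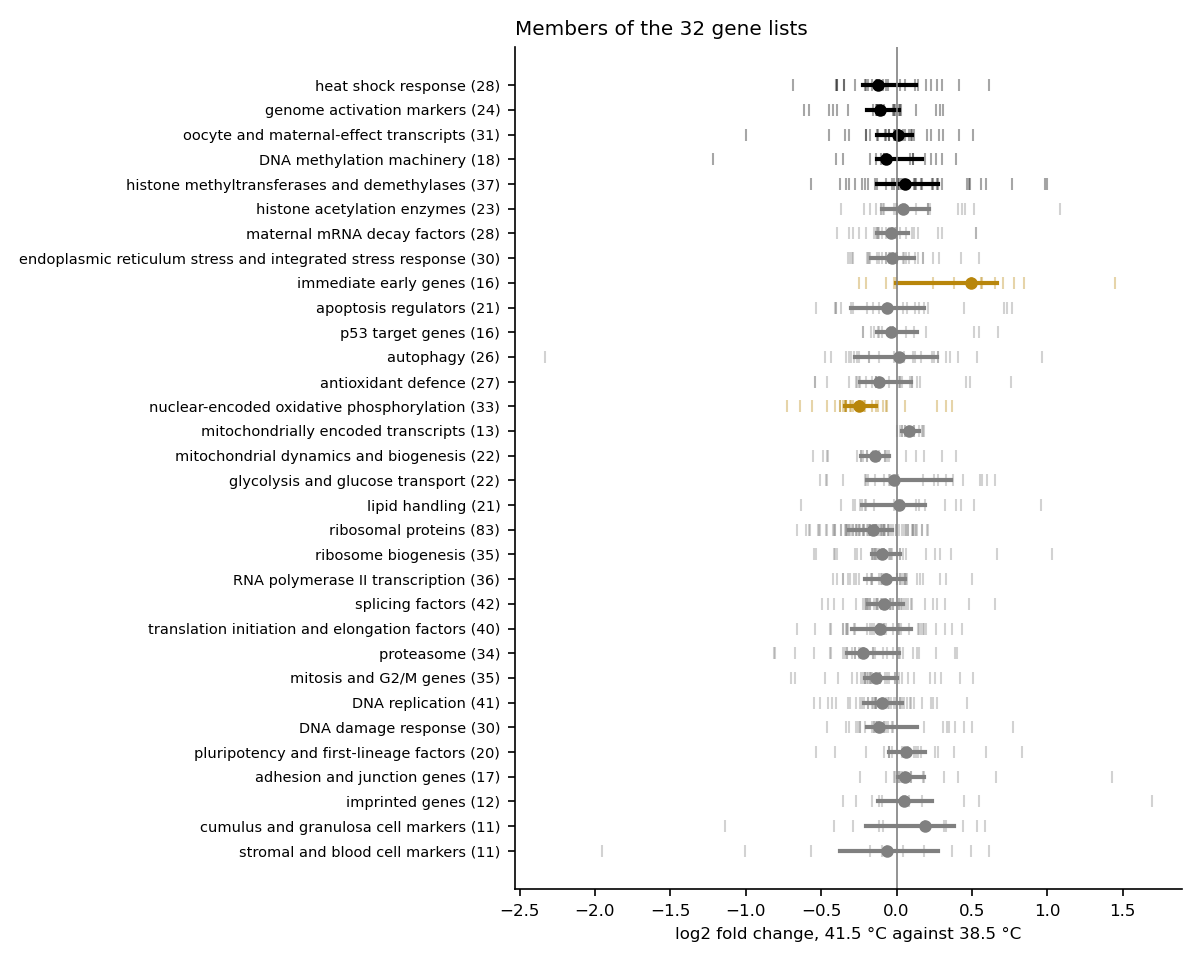
Log2 fold change (x axis) at 41.5 °C against 38.5 °C for each measured member (ticks) of the 32 gene lists, with the median (point) and the middle of the distribution between the quartiles (bar), and the number of members in brackets. Lists with a camera adjusted p below the threshold are in ochre (immediate early genes, median 0.50, and nuclear-encoded oxidative phosphorylation, median -0.25), the 5 primary lists in black and the rest in grey.

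None of the remaining lists was called by camera with the preset correlation over all 6 libraries, with group as the single term. The adjusted p was 0.986 for endoplasmic reticulum stress and the integrated stress response, 0.737 for apoptosis regulators and for p53 target genes, 0.742 for autophagy, 0.384 for antioxidant defence, 0.51 for DNA damage response, 0.696 for glycolysis and glucose transport, and 0.77 for lipid handling and for maternal mRNA decay factors. It was 0.282 for mitochondrial dynamics, 0.673 for ribosome biogenesis, 0.659 for RNA polymerase II transcription, 0.51 for splicing factors and for translation factors, 0.51 for pluripotency and first-lineage factors, and 0.298 for adhesion genes and for imprinted genes. The median and the mean differed in sign for apoptosis regulators (-0.07 and 0.01), p53 targets (-0.03 and 0.06), autophagy (0.02 and -0.05) and glycolysis (-0.01 and 0.07), and the sign of each of these 4 medians also changed under another scaling. With a library left out some of these lists were called. Without high-temperature replicate 1 mitochondrial dynamics (adjusted p = 0.00922), ribosome biogenesis (0.0251), splicing factors (0.00517) and translation factors (0.000391) were called lower. The same held for ribosome biogenesis (0.0229) and translation factors (0.00241) without control replicate 3. Translation factors (0.0378) and the histone acetylation enzymes (0.0432) were called higher without control replicate 1. Adjusted over the list alone, IGF2 among 12 imprinted genes was the single member of any list that passed.

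Markers of cells that could have been carried over with the embryos were compared as sums, for which 3 against 3 libraries allow no exact p below 0.1. The 11 measured cumulus and granulosa cell markers summed to 45.5 ± 3.29 CPM in controls and 52.0 ± 4.99 CPM at high temperature (SD, n = 3; exact permutation test, two-sided p = 0.2), and the 11 stromal and blood cell markers to 16.4 ± 1.25 and 16.2 ± 1.83 CPM (exact p = 0.9). The camera adjusted p was 0.335 for the cumulus list, which was called higher on the FPKM scale (adjusted p = 0.00835) and the TPM scale (0.0103), and 0.51 for the stromal and blood list, which was called lower without high-temperature replicate 1 (0.0474).

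Oocyte transcripts and ribosomal protein transcripts varied more between libraries of a group than between the groups. The mean log2 CPM of the oocyte list ranged from 4.90 (control replicate 1) to 5.72 (control replicate 3) in controls and from 5.11 to 5.69 at high temperature (exact permutation test, two-sided p = 1, where no p below 0.1 is possible). That of the genome activation list ranged from 5.73 to 6.38 in controls and from 5.55 to 6.26 at high temperature, highest in the libraries with the lowest oocyte mean (exact p = 0.7). Ribosomal protein genes had a mean log2 CPM of 7.28 in control replicate 1 and 5.66 in high-temperature replicate 3. The 18S ribosomal RNA gene RN18S, an abundant RNA without a poly(A) tail named after its values were seen, was at 105, 347 and 554 CPM in control replicates 1, 2 and 3 and at 218, 422 and 968 CPM in those at high temperature. The first principal component, with 52.1% of the variance, placed replicate 1 of both groups at one end and replicate 3 of both at the other, and the second, with 16.4%, parted the groups (exact p = 0.1). Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.936 to 0.976 within groups and 0.929 to 0.981 between them.

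**Figure D5:**
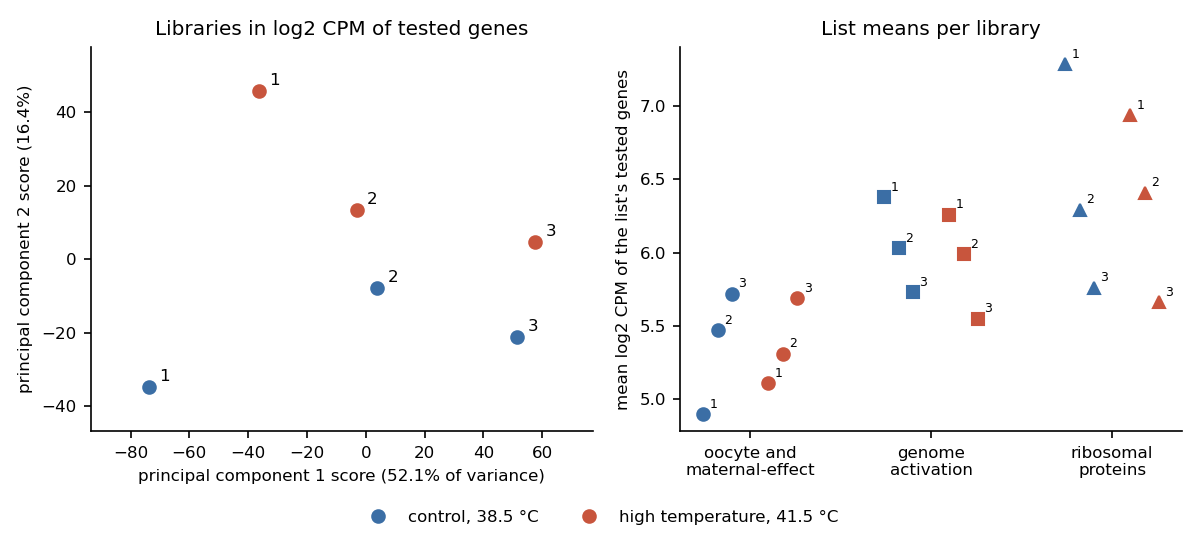
Left, the 6 libraries by their scores on the first (52.1% of variance) and second (16.4%) principal components of log2 CPM, with replicate numbers. Right, the mean log2 CPM (y axis) of the oocyte, genome activation and ribosomal protein lists in each library, where control replicate 1 has the lowest oocyte mean (4.90) and the highest ribosomal mean (7.28).

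Fold changes also shifted with abundance. Genes under 1 CPM had a median log2 fold change of 0.11 with 58.6% higher at high temperature, and genes over 64 CPM a median of -0.12 with 23.6% higher. The libraries at high temperature had counts for 20600 ± 166 genes against 20200 ± 287 in controls, and their 10 most abundant genes took 28 ± 0.289% of the counts against 26 ± 0.520%, both without overlap (SD, n = 3; exact permutation test, two-sided p = 0.1).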

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

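The covariates (list score, component and svaseq), the robust fit, the fit to nuclear genes only and the oxidative phosphorylation list with renamed members were chosen after the data were seen. No gene was called in 13 of 19 alternatives, among them each library left out. The count was 5 with DESeq2, 1 with no filter on low counts, 5 with the list score covariate, 10 with the component covariate and 5 with svaseq. WISP3 was called in 6 alternatives (adjusted p from 7.86e-15 to 1), LSMEM2 and MOGAT1 in 5, WDR76 in 4, LOC110260131 in 3, and BZW1, FKBP3, LOC100525232, LOC110262067, PSMB6 and PTTG1 in 1 each. The 10 genes with the smallest p kept their sign throughout. They were chosen by p in these same libraries and their groups do not overlap, so this was largely fixed beforehand. Of 402 values of named genes 34, in 9 genes, had the other sign. Against 2 lists called by camera, 4 were called on log2(FPKM + 1) and 4 on log2(TPM + 1), 6 with the list score covariate, 6 with the component covariate, 6 with svaseq, 2 with renamed members, 0 with an estimated correlation and 0 by fry, and from 1 (without high-temperature replicate 3) to 10 (without high-temperature replicate 1) with a library left out. The proteasome and mitosis lists were among those called with each of the 3 covariates, and DNA replication and mitochondrially encoded transcripts with the list score and svaseq. The immediate early list kept its call in 18 of 20 alternatives (adjusted p from 6.03e-05 to 0.285) and the oxidative phosphorylation list in 16 (1.45e-06 to 0.929). Without control replicate 1, ribosomal proteins (adjusted p = 4.42e-06) and translation factors (0.0378) were called in the other direction. With each library left out the adjusted p of these lists ranged from 4.91e-09 to 0.236 and from 0.000391 to 0.462. The median correlation of replicates was 0.965, and 0.934 with a prior count of 0.1. The cause of these differences was not tested. The alternatives written for a series with normalized values alone, such as other pseudocounts, were not run, as counts were given.

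With the replicate block 3 genes were called (MOGAT1 higher, WISP3 and LSMEM2 lower), all 3 of them also called by DESeq2, and 5 lists: immediate early genes, oxidative phosphorylation, mitochondrial dynamics (adjusted p = 0.0467), ribosomal proteins (0.0139) and the proteasome (0.00156). The labels do not say that the numbers pair the libraries, and the main fit did not pair them. The deviations from the group means correlated at 0.52, 0.008 and 0.59 between libraries of the same number, and control replicate 2 correlated best with high-temperature replicate 3 (0.079). Both replicate 2 libraries lay near their group mean on the first component of these deviations (scores 9.67 and -8.72), so the 0.008 cannot decide against pairing. As a hint from the data, the chi-square per degree of freedom between the groups was lowest for libraries of the same number in all 3 numbers (48.7, 24.8 and 20.1). Their Pearson correlations were 0.97, 0.981 and 0.979. A pairing or a batch by number stays open.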

Other observations

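The tests of overlapping genes, of transcript length and abundance, of progress from oocyte to embryonic transcripts and of the heat shock list were chosen only after the results were seen, and so were the patterns weighed and the bounds under which the thinning and scaling tests decide nothing.

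The genes with the smallest p may in part reflect how reads were divided between overlapping genes, a hypothesis tested on the summed counts. Against it, the sum of WDR76 and FRMD5 kept a log2 fold change of -0.81 (95% interval -1.2 to -0.41). For MOGAT1 the sum was at -0.028 (-0.55 to 0.50), for LSMEM2 at 0.031 (-0.75 to 0.81) and for WISP3 at -0.18 (-0.70 to 0.35), and these intervals also hold the values predicted with the overlapping genes unchanged (0.41, -0.46 and -0.25), so the explanations cannot be told apart. With the list score as a covariate the sums were at -0.052 (-0.40 to 0.29), -0.054 (-0.37 to 0.27) and -0.22 (-0.51 to 0.06), which leave out the predicted value for MOGAT1 and LSMEM2 but not for WISP3. An effect of culture temperature on these genes stays open.

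Libraries of both groups spread along 1 component of the deviations from the group means, with 60.7% of their variance, and no difference between library batches was tested, as the labels give none. The difference of median slope between the oocyte and genome activation lists, 0.65, lay at percentile 100 of random pairs matched on transcript length and abundance (95% range -0.27 to 0.27). Length and abundance are argued against for this difference alone, as the test did not ask what made the component. The random lists also lack the correlation within the real ones (0.51 and 0.38), so their range may be too narrow. Across genes the Spearman correlation of slope and length was 0.05. A candidate explanation for the component is that embryos of a library lay further or less far along the change from oocyte to embryonic transcripts. The component was made without the genes of both lists, but its sign was set by the oocyte list. A positive slope of most oocyte genes was thus chosen, while the size of the shares and the opposite sign of the activation genes were not. Of the oocyte genes 27 of 31 (87.1%) had a positive slope and 20 of 24 activation genes (83.3%) a negative one on this component. Other lists, whose genes helped to make it, followed it in as large a share of their members, with negative slopes for 82 of 83 ribosomal protein genes (median slope -0.65, against -0.30 for activation genes), 37 of 40 translation factors, 31 of 33 oxidative phosphorylation genes and 13 of 13 mitochondrially encoded transcripts, so the component does not single out this hypothesis, which was found and tested on the same data. The share was 61% after thinning to about the smallest total, but thinning removed little, so the bound of 50% set beforehand was wrong in counting this against library size. Other values argue against unequal depth as the cause. The largest total was only 1.07 times the smallest, while the ribosomal list mean ran from 7.28 to 5.66 log2 CPM. Control replicate 3 and high-temperature replicate 1, with 28869484 and 28892695 reads, had list means of 5.76 and 6.94. Within each group the order of the totals followed the component, so a property that goes with the total stays open.

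No heat shock gene was called by edgeR, where 297 of all genes had an unadjusted p below 0.05 and DESeq2 also called no member. Spread between libraries as a cover for a 2-fold rise of the list relative to other genes is argued against, since with the list score as a covariate the interval of 26 of the 28 members excluded such a rise. Scaling stays open: the highest median log2 fold change over 5 scalings was 0.0054, but they moved the median of all genes by at most 0.094, and each sets a library against its own counts, so a rise shared by most genes would not show. A rise that had ended before collection was not tested.

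The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes called the real value was 0 and the highest other 0 (10 of 10 splits as large), for lists called by camera 2 and 13 (8 of 10), and for genes called with the component covariate 10 and 3730 (5 of 10). With the component covariate 4 other splits called several times the real count (158, 1201, 2822 and 3730 genes), which points to a structure of the samples whose cause was not tested. The covariate was made anew in each split and held 41.8% to 60.7% of the variance of its deviations.

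The called lists were first weighed as a further pattern, in 4 tests that were withdrawn from the weighing after their outcomes were known, and their values are given here without a verdict. Against random lists matched on abundance and length, the immediate early median of 0.50 lay at percentile 100 and the oxidative phosphorylation median of -0.25 at percentile 1.35. The latter was -0.16 with the list score as a covariate, and 0.027 without control replicate 1, its value nearest to or past 0 with a library left out.

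Of the positioned genes with an unadjusted p below 0.05, 117 of 284 (41.2%) overlapped another counted gene, against 34.7% of the others (Fisher's exact test across genes, which are not independent, two-sided p = 0.0236). NCBP2, singled out after its values were seen, had 13777, 8366 and 0 counts in controls and 10925, 8125 and 4739 at high temperature, and the overlapping PIGZ had 0, 0 and 5749, and 142, 0 and 2. PCDHA11, MRPL53 and LOC106506288 also had 0 counts in 1 library with a median above 300.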
